A study of Mus musculus with 10 samples.

How the data were processed

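Transcripts were measured by bulk RNA sequencing in cultured peritoneal macrophages of 5 CTR and 5 Mac-GsαKO libraries from mice aged 6 to 8 weeks. Per the labels, total RNA was isolated with an RNeasy kit and made into libraries by standard Illumina protocols. The authors' processing notes name CASAVA 1.8, HISAT2, SAMtools 1.3.1, edgeR and the genome build GRCm39, with no order or role. The read counter, the annotation release, the strand setting and the versions of HISAT2 and edgeR are not given in the sources used here. The deposited table holds raw counts per Ensembl gene, as whole numbers, and FPKM values by the authors. The deposited FPKM equal the counts divided by gene length and scaled to the column's total count, with a relative deviation of at most 1.2e-05 where a gene had at least 50 counts. The FPKM values served only to recover the gene length the authors used, which was not stated.

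Every one of the 20 columns was assigned to its sample by the library number in the labels. The table held 53465 genes, of which 53274 were matched to a symbol by their identifier and 191 were not, which held 0.0403% of the counts. Symbols came from a separate list of gene names. GC content came from GENCODE M21 (longest transcript per gene) and gene order from RefSeq, both on GRCm38. That is another build than the one the authors name, so no coordinates are given. Totals ranged from 15664243 to 18028974 counts in CTR and from 16877249 to 19235777 counts in KO. The upper limit that a count of 0 allows was taken as 3 counts per library. Reads without molecular identifiers are not independent molecules, so such limits cover counting error only.

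Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with its defaults, which left 13203 genes holding 99.9% of the counts, and libraries were scaled by TMM. The genotypes were compared by the edgeR quasi-likelihood test, two-sided, with genotype as the only term, and p-values were adjusted by the method of Benjamini and Hochberg over all genes tested, with a threshold of 0.05. Standard errors of log2 fold changes were the absolute log2 fold change over the square root of the F statistic. CPM were computed on TMM-scaled library sizes. The biological coefficient of variation was 0.200. Gnas, Lyz2 and Lyz1 were also compared by a two-sided exact permutation test of log2 CPM. The labels do not say whether equal replicate numbers pair samples, so no pairing was used in the main fit. Residuals of equal numbers correlated between -0.126 and 0.0582 across genes. Genes are not independent replicates, so this cannot exclude pairing.

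The design, the comparisons, the 32 gene lists, the rule for named genes and the other settings to be tried, apart from those named as added, were fixed before the data were examined. The rule named 7 genes whatever their result (Gnas, Lyz2, Cd36, Msr1, Abca1, Abcg1 and Soat1). It then named the 8 genes with the largest rise and the 8 with the largest fall among those with an adjusted p under 0.05, an average log2 CPM of at least 1 and no overlap between the genotypes, leaving out predicted genes, clone names and immunoglobulin or T cell receptor segments. Last, it named up to 3 members with the lowest p of each list that passed or had a called member. Cd74, Timd4, Selp and Cd5l are list members outside this rule, chosen after their values were seen. Some results, among them 1 that the rule takes, are not reported here. Lists with at least 5 tested members were tested by camera on voom values with an inter-gene correlation preset to 0.01, two-sided and adjusted over the lists, and again with an estimated correlation and by fry. Member counts are given over all genes tested and adjusted over the list alone.

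The lists covered cAMP pathway components, Gs-coupled receptors, CREB targets, lipoprotein uptake, cholesterol efflux and LXR targets, cholesterol biosynthesis, lipid storage, inflammatory mediators, interferon-stimulated genes, alternative activation, MHC class II, resident and small peritoneal macrophages, cell cycle, matrix proteases, lysosome, unfolded protein response, oxidative phosphorylation, glycolysis and hypoxia, chemotaxis and adhesion, core macrophage genes, heat shock and early stress, and markers of B, T and NK, neutrophil, mast, eosinophil, dendritic, mesothelial, fibroblast and erythroid cells, with sex-linked genes. Some genes stand in more than 1 list, such as Thbs1 and Itgam.

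Other settings tried were DESeq2 size factors, library size only, no filter on low counts, a CPM of at least 1 in at least 5 libraries, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, a robust quasi-likelihood fit, the replicate number as a block, and each library left out in turn. After the data were seen, a fit without CTR 4 and CTR 5 and a correction of each library for a smooth trend on gene length and GC content (mgcv 1.9.3) were added. The test was run on simulated data with the libraries' own depths and dispersions and 200 changed genes, where 89 genes were called and 2 of these (2.25%) were false. The 10 libraries were also split in 100 ways into 5 and 5, the real split included, with a fixed seed. GC content was read with Biostrings 2.70.1, tables were read with data.table (version 1.17.8), and figures were drawn with Python 3.11.15 and matplotlib 3.10.9.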

Results

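RNA was sequenced from cultured peritoneal macrophages of control mice (CTR, 5 libraries) and of Mac-GsαKO mice (KO, 5 libraries), which per their name lack Gsα in macrophages. Gsα, encoded by Gnas, is the stimulatory G protein subunit that couples receptors to adenylyl cyclase. The mice were aged 6 to 8 weeks, and the cells received no added treatment. The libraries are named here by genotype and replicate number. CTR 1 held 18028974 counts, CTR 2 held 16975377, CTR 3 held 17720806, CTR 4 held 16315462 and CTR 5 held 15664243. KO 1 held 17053488 counts, KO 2 held 19235777, KO 3 held 16877249, KO 4 held 17649236 and KO 5 held 17217846. At this depth 3 counts, the upper limit that a count of 0 allows, came to between 0.154 and 0.203 CPM (counts scaled to a common library total), for counting error only. The labels do not say that each library came from a separate mouse, so errors and p-values measure the spread between these libraries. Values below are means ± SD over the 5 libraries of a genotype, and log2 fold changes are KO over CTR with their standard error (SE).

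All 5 KO libraries lay on the positive side of the first principal component, between 11.6 and 28.7, and all 5 CTR libraries on the negative side. The first component held 26.3% of the variance and the second held 19.5%. CTR 4 and CTR 5 lay apart from the other CTR libraries, both at -34.7 on the first component, and CTR 4 also at -46.7 on the second. CTR 4 had 17894 genes with at least 1 count, against 18430 ± 308 over the CTR libraries and 18774 ± 126 over the KO libraries. Mitochondrially encoded genes held 1.70 ± 0.207% of the counts in CTR and 1.29 ± 0.0605% in KO.

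**Figure D1:**
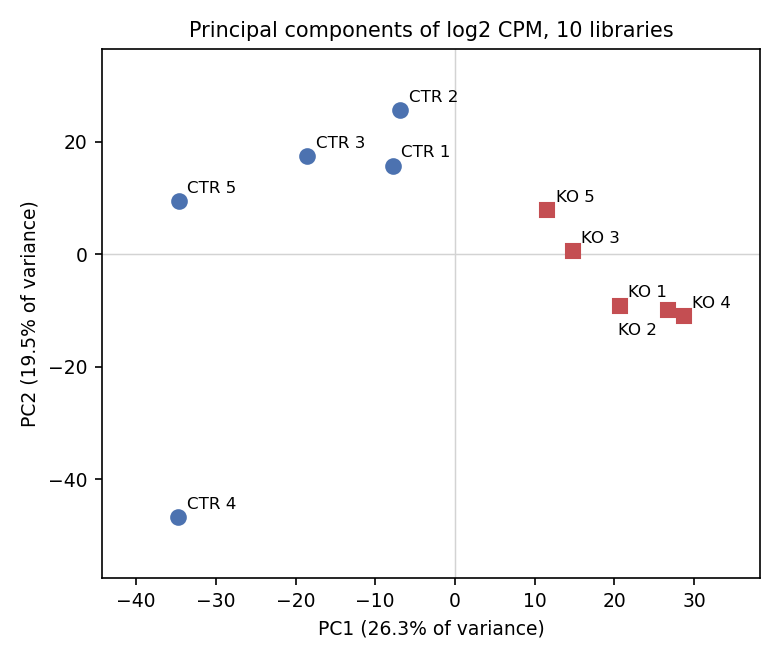
First against second principal component of log2 CPM over the genes tested, 1 point per library, coloured by genotype (5 CTR, 5 KO). The KO libraries lie together at 11.6 to 28.7 on the first component, and CTR 4 and CTR 5 lie apart at -34.7.

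The comparison of KO with CTR addressed which transcripts differ in macrophages without Gsα, in a study of foam cells, the lipid-laden macrophages of atherosclerotic vessels. Gnas (ENSMUSG00000027523) fell from 435 ± 62.4 CPM in CTR to 40.2 ± 2.62 CPM in KO, a log2 fold change of -3.43 (SE 0.11) or 10.8-fold lower (adjusted p = 9.16e-09). Lyz2 (ENSMUSG00000069516), the lysozyme gene of macrophages, fell from 26528 ± 3802 to 9240 ± 517 CPM, a log2 fold change of -1.52 (SE 0.10, adjusted p = 2.03e-05). Lyz1 (ENSMUSG00000069515), the lysozyme gene best known from Paneth cells, rose from 161 ± 38.5 to 672 ± 134 CPM, a log2 fold change of 2.06 (SE 0.18, adjusted p = 0.000230). The Lyz1 and Lyz2 sequences are close to each other, and reads may be assigned to either. For each of Gnas, Lyz2 and Lyz1 the 5 libraries of one genotype lay beyond all 5 of the other, with a two-sided exact permutation p of 0.00794, the smallest that 252 arrangements can give. Lyz1 was named by a rule that requires this separation, so its permutation p followed from its choice. Gnas and Lyz2 were fixed by name. A gene-level count of Gnas covers exons outside any deleted part and other transcripts of the locus, so it does not measure the protein that remained.

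Of the 13203 genes tested, 241 rose and 279 fell in KO at an adjusted p under 0.05, and 63 of each changed at least 2-fold. With library-size scaling alone the counts were 312 and 213, a share of 59.4% higher against 46.3% with TMM. At an unadjusted p under 0.05, 2895 genes differed. In 444 of the 520 called genes all libraries of one genotype lay above all of the other. Over all genes tested this held for 7.80%, against 0.794% by chance. The genes that fell were shorter, with a median length of 2531 bases against 6425 for those that rose and 5622 for the rest, and their median GC content was 48.3% against 53.7% for those that rose. The ratio of these median lengths, 2.54 with all libraries, was 0.958 over the genes called without CTR 4 and CTR 5 (medians 3990 and 4167), 0.970 with the length and GC correction, and 2.51 over the genes called both with and without CTR 4 and CTR 5. Among 997 pseudogenes tested, 27 rose and 61 fell, and reads of a pseudogene may come from its parent gene. The number of calls depended on single libraries: it was 121 without CTR 3, 131 without KO 1, 62 without KO 2, 127 without KO 4, 320 without KO 3 and 868 without CTR 4, and the number of higher genes was 156 without CTR 1. Without CTR 4 and CTR 5 together it was 1185, and 60 genes (31 higher, 29 lower) kept their call in all 10 fits that left out 1 library.

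The genes with the largest rises that separated the genotypes, besides Lyz1, included transporter and receptor genes. Slco2b1, an organic anion transporter, rose from 13.8 ± 3.50 to 38.0 ± 10.8 CPM (log2 fold change 1.46, SE 0.21, adjusted p = 0.00666). Adrb1, a beta-adrenergic receptor that couples to Gsα, rose from 1.98 ± 0.699 to 5.41 ± 1.85 CPM (1.45, SE 0.30, adjusted p = 0.0246). Flt1, a receptor for vascular endothelial growth factor, rose by a log2 fold change of 2.01 (SE 0.40, adjusted p = 0.0216). Rtl5, a gene derived from a retrotransposon, rose by 1.52 (SE 0.32, adjusted p = 0.0268), Ankdd1a by 1.52 (SE 0.34, adjusted p = 0.0315) and Tmem178 by 1.61 (SE 0.38, adjusted p = 0.0388). Slco2b1 kept its call with any 1 library left out. The other 5 of these genes lost it without CTR 3, KO 1, KO 2 or KO 4, with adjusted p up to 0.0614 for Flt1, 0.0647 for Adrb1, 0.0777 for Rtl5, 0.0906 for Ankdd1a and 0.101 for Tmem178. Ankdd1a also lost it without CTR 1, and Tmem178 without CTR 1, CTR 5 or KO 3.

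The genes with the largest falls besides Gnas included several of resident peritoneal macrophages. Serpinb2, an inhibitor of plasminogen activators, fell from 21.3 ± 11.04 to 3.58 ± 0.738 CPM (log2 fold change -2.57, SE 0.31, adjusted p = 0.00297). Alox15, a lipoxygenase, fell from 20.7 ± 9.89 to 3.99 ± 1.25 CPM (-2.37, SE 0.34, adjusted p = 0.00666). Thbs1, which encodes the matrix glycoprotein thrombospondin, fell from 269 ± 113 to 52.4 ± 25.8 CPM (-2.36, SE 0.36, adjusted p = 0.00848). Ltbp1, which encodes a binding protein of latent TGF-β, changed by -2.02 (SE 0.39, adjusted p = 0.0205), and Timp1, an inhibitor of matrix metalloproteinases, by -2.12 (SE 0.51, adjusted p = 0.0406). The ribosomal protein pseudogene Rpl35a-ps3 changed by -2.22 (SE 0.36, adjusted p = 0.0110) and the mitochondrial alanine tRNA mt-Ta by -1.89 (SE 0.26, adjusted p = 0.00585), and both are short transcripts whose reads other loci can share. Serpinb2, Alox15, Thbs1, Rpl35a-ps3 and mt-Ta kept their call with any 1 library left out. Ltbp1 lost it without CTR 3, KO 1 or KO 4 (adjusted p up to 0.0579) and Timp1 without CTR 3 or any 1 of the KO libraries (up to 0.108). Timp1 stood at 44.7 CPM in CTR 5 and between 6.48 and 11.6 CPM in the other CTR libraries, and its log2 fold change was -1.26 without CTR 5. Without CTR 4 and CTR 5 the log2 fold changes were -2.04 for Serpinb2, -1.79 for Alox15, -1.33 for Timp1 and -1.60 for Rpl35a-ps3. In that fit Thbs1 had -2.57, Ltbp1 -1.88 and mt-Ta -1.75.

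**Figure D2:**
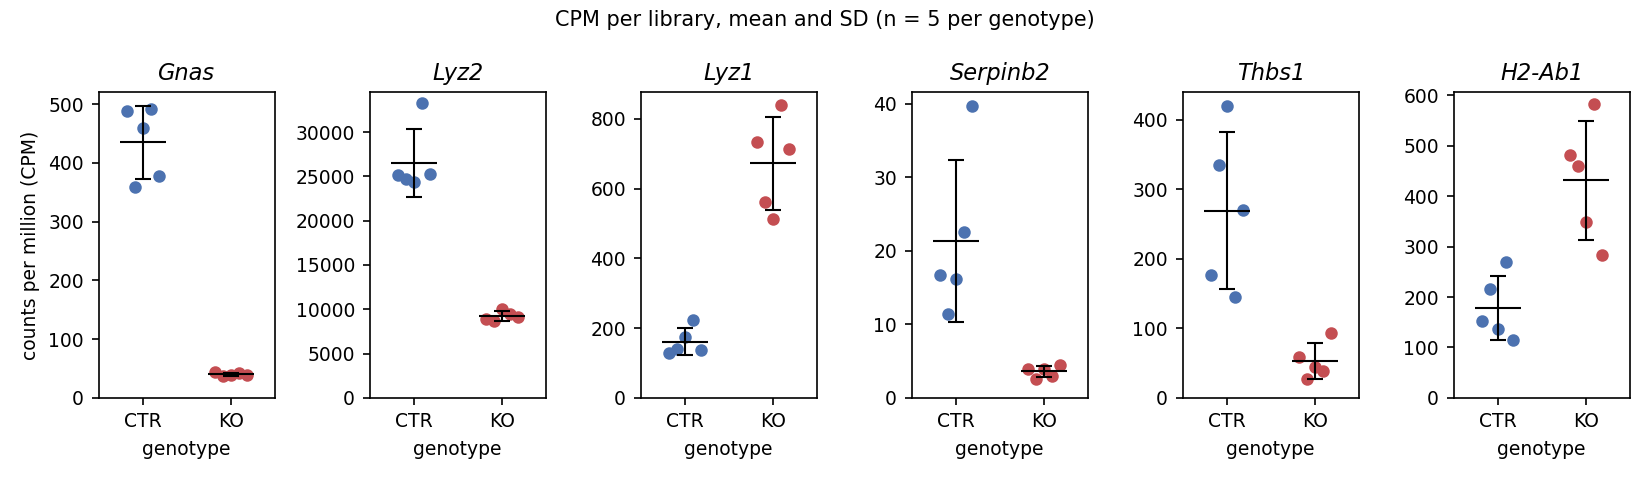
CPM per library (points) with mean and SD (lines) for Gnas, Lyz2, Lyz1, Serpinb2, Thbs1 and H2-Ab1 in 5 CTR and 5 KO libraries, on linear axes from 0. Gnas stood between 359 and 491 CPM in CTR and between 37.0 and 43.5 CPM in KO.

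**Figure D3:**
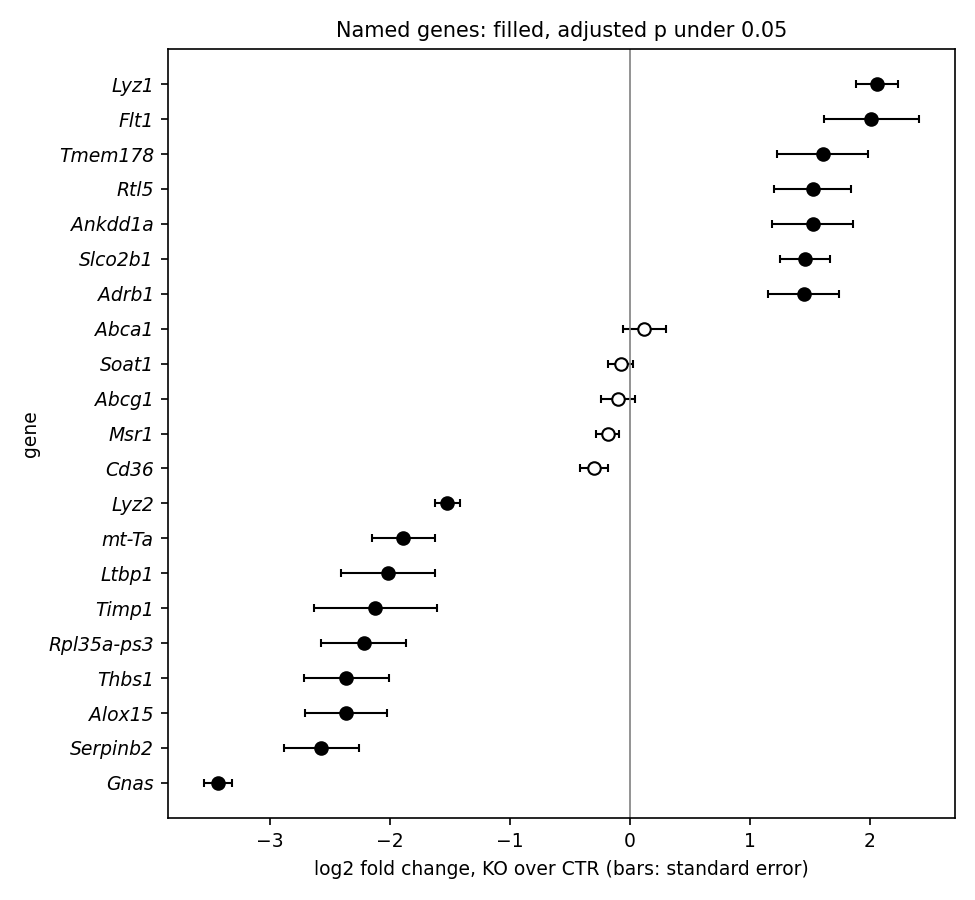
Log2 fold change, KO over CTR, with its SE for the genes fixed by name and for genes with the largest changes, 5 libraries per genotype. Filled points have an adjusted p under 0.05. Gnas stands lowest at -3.43 and Lyz1 highest at 2.06.

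The genes fixed by name for foam cells did not pass the test in the main fit. Cd36, a scavenger receptor for oxidised lipoprotein, stood at 2175 ± 208 CPM in CTR and 1768 ± 315 CPM in KO (log2 fold change -0.30, SE 0.12, adjusted p = 0.170, and 0.0464 without KO 5). It passed in 2 of 20 other settings, with an adjusted p down to 0.0410. Msr1, another scavenger receptor, had a log2 fold change of -0.19 (SE 0.10, adjusted p = 0.288). The cholesterol exporters Abca1 and Abcg1 had log2 fold changes of 0.12 (SE 0.18, adjusted p = 0.731) and -0.10 (SE 0.14, adjusted p = 0.725), and that of Abca1 was -0.01 without CTR 5. Soat1, which esterifies cholesterol, had -0.08 (SE 0.11, adjusted p = 0.705). Without CTR 4 and CTR 5 Soat1 had -0.23 (adjusted p = 0.0438), Abcg1 -0.27 (adjusted p = 0.0927), Abca1 -0.13 (adjusted p = 0.434) and Msr1 -0.07 (adjusted p = 0.5999). Changes of this size were below what 5 libraries per genotype resolve well: in simulated data with this spread, 20% of 1.5-fold changes were called and 67% of 2-fold changes.

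Single members of the lipid lists changed while the lists as a whole did not pass camera. With fry the lipid storage list passed downward (adjusted p = 0.0334). Lpl, which encodes lipoprotein lipase, rose from 2006 ± 598 to 3229 ± 239 CPM (log2 fold change 0.69, SE 0.17, adjusted p = 0.0430), and the endocytic receptor Lrp1 rose from 1256 ± 332 to 2137 ± 267 CPM (0.77, SE 0.18, adjusted p = 0.0376). Pltp, which encodes the phospholipid transfer protein, rose by 0.75 (SE 0.17, adjusted p = 0.0362). Plin2, the coat protein of lipid droplets, fell from 2112 ± 191 to 1531 ± 242 CPM (-0.46, SE 0.11, adjusted p = 0.0430), and the fatty acid binding protein gene Fabp5 fell from 3592 ± 317 to 2678 ± 175 CPM (-0.42, SE 0.09, adjusted p = 0.0236). In the list of lipid storage and fatty acid metabolism 1 of 24 members rose and 2 fell (1 and 3 adjusted over the list alone, list adjusted p = 0.268). Of 17 lipoprotein uptake receptors 1 rose (1 adjusted over the list alone, list adjusted p = 0.784), and of 21 genes of cholesterol efflux and LXR targets 1 rose (1 adjusted over the list alone, list adjusted p = 0.449). Of 25 genes of cholesterol biosynthesis only Tmem97, a sterol-regulated membrane protein gene, fell (-0.42, SE 0.09, adjusted p = 0.0273; 1 adjusted over the list alone). That list had an adjusted p of 0.519, and of 0.0157 without KO 5. All 6 of these genes lost their call without CTR 3, KO 1, KO 2 or KO 4, with adjusted p up to 0.108 for Lpl, 0.0990 for Lrp1, 0.105 for Pltp, 0.104 for Plin2, 0.0745 for Fabp5 and 0.0865 for Tmem97. Lpl, Lrp1, Pltp and Plin2 also lost it without CTR 1, Lpl, Pltp and Plin2 without CTR 2 or CTR 5, Lpl, Lrp1 and Plin2 without KO 5, and Lpl and Pltp without KO 3. With the length and GC correction Lrp1 (0.46, adjusted p = 0.110) and Lpl (0.64, adjusted p = 0.0751) lost their call, and with library-size scaling alone Plin2 did (adjusted p = 0.0687). At an adjusted p under 0.05, 1 lipid storage gene was higher and 3 lower by DESeq2, and 1 and 4 by voom. Lipoprotein uptake had 2 and 0 by DESeq2, and 2 and 2 by voom. Cholesterol efflux had 1 and 0, and 2 and 1. Cholesterol biosynthesis had 0 and 1, and 2 and 3.

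Apart from Gnas, few genes of the Gs and cAMP pathway passed the test. Adcy9, an adenylyl cyclase, rose from 7.85 ± 1.72 to 12.5 ± 1.05 CPM (log2 fold change 0.67, SE 0.16, adjusted p = 0.0388). Of 35 cAMP pathway components, Gnas included, Adcy9 rose and the 1 that fell was Gnas itself (3 and 2 adjusted over the list alone, list adjusted p = 0.353). In value 24 members were higher and 11 lower. With Gnas in the list, fry gave the opposite direction to camera. Of 10 Gs-coupled receptors Adrb1 rose (2 adjusted over the list alone, list adjusted p = 0.0596). Of 22 CREB target genes Thbs1 fell (1 higher and 1 lower adjusted over the list alone, list adjusted p = 0.101), while the list median was 0.25. The receptor list passed in 3 of 10 fits that left out 1 library, those without CTR 4, KO 3 or KO 4 (adjusted p down to 0.0354). It also passed with the length and GC correction (0.0143), but not without CTR 4 and CTR 5 (0.0902). The CREB list passed in 1 of these 10 fits, without CTR 4 (0.0260). It also passed without CTR 4 and CTR 5 (0.0479) and with voom quality weights (0.0271), but not with the length and GC correction (0.168). Adcy9 lost its call without CTR 3, CTR 5 or any 1 of the KO libraries (adjusted p up to 0.110), and with the length and GC correction (0.0689).

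Genes of antigen presentation by MHC class II passed upward as a list with camera at a preset correlation and with fry, but not with camera at an estimated correlation. H2-Ab1 rose from 178 ± 63.8 to 432 ± 117 CPM (log2 fold change 1.28, SE 0.25, adjusted p = 0.0204) and H2-Aa from 240 ± 81.0 to 573 ± 144 CPM (1.25, SE 0.24, adjusted p = 0.0205), the genes of an MHC class II pair that presents peptides. Cd74, the invariant chain, rose from 560 ± 222 to 1239 ± 242 CPM, and H2-DMb1, a peptide exchange factor, rose from 56.6 ± 7.99 to 96.2 ± 24.8 CPM (0.77, SE 0.17, adjusted p = 0.0293). Of 9 members 6 rose and none fell (9 and 0 adjusted over the list alone), with a median log2 fold change of 1.14, and by edgeR none of the 9 was lower at an unadjusted p under 0.05, nor at an adjusted p under 0.05 by DESeq2 or voom. The list passed camera (adjusted p = 7.43e-08, adjusted p = 0.340 with an estimated correlation). Its median was 1.13 without CTR 4 and CTR 5, with a camera adjusted p of 3.29e-06. H2-Ab1, H2-Aa and H2-DMb1 lost their call without CTR 3, KO 1, KO 2 or KO 4 (adjusted p up to 0.0591, 0.0591 and 0.0803), and H2-DMb1 also without CTR 1 or CTR 5. The B cell markers, which also mark cells with MHC class II, had a median of 0.58, with Cd79a at 0.588 ± 0.334 CPM in CTR and 1.33 ± 0.437 CPM in KO.

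Markers of resident large peritoneal macrophages passed downward as a list with camera at the preset correlation, but not at an estimated correlation or with fry (adjusted p = 0.0577). Besides Serpinb2, Alox15, Thbs1 and Ltbp1, Timd4, a receptor for phosphatidylserine, fell from 2.25 ± 1.02 to 0.702 ± 0.279 CPM, and Selp, which encodes P-selectin, from 3.14 ± 1.37 to 0.988 ± 0.641 CPM. Of 20 members 6 fell and none rose (8 and 1 adjusted over the list alone), and at an unadjusted p under 0.05 in edgeR 3 were higher. At an adjusted p under 0.05, 1 was higher by DESeq2 and 2 by voom. Cd5l, an apoptosis inhibitor of macrophages, stood at 273 ± 126 CPM in CTR and 460 ± 116 CPM in KO (adjusted p = 0.122). The list median was -0.68, and the list passed camera (adjusted p = 0.00294, adjusted p = 0.416 with an estimated correlation). Its median was -0.37 without CTR 4 and CTR 5, with a camera adjusted p of 0.0902. Of 15 markers of small peritoneal and monocyte-derived macrophages Clec4b1, a C-type lectin gene, rose (1.38, SE 0.31, adjusted p = 0.0315; 4 higher and 1 lower adjusted over the list alone). That list had an adjusted p of 0.0548, and of 0.0223 without KO 4. Clec4b1 lost its call without any 1 of CTR 1, CTR 2, CTR 3 and KO 1 to KO 4 (adjusted p up to 0.0852).

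As lists, glycolysis and hypoxia response genes passed upward and oxidative phosphorylation genes downward with camera at the preset correlation, but neither at an estimated correlation or with fry (adjusted p = 0.0844 and 0.144). Hk2, a hexokinase, rose from 119 ± 23.6 to 204 ± 21.1 CPM (log2 fold change 0.77, SE 0.13, adjusted p = 0.0139), and Gpi1, which encodes glucose phosphate isomerase, from 390 ± 111 to 624 ± 84.1 CPM (0.68, SE 0.17, adjusted p = 0.0443). The lactate transporter gene Slc16a3 had 0.78 (SE 0.20, adjusted p = 0.0502). Of 24 glycolysis and hypoxia genes 2 rose (9 adjusted over the list alone, median 0.38), and the list passed camera (adjusted p = 9.14e-08, adjusted p = 0.416 with an estimated correlation). Without CTR 4 and CTR 5 its camera adjusted p at the preset correlation was 2.33e-12 and its median 0.57. The respiratory chain genes Ndufa4 (-0.55, SE 0.12, adjusted p = 0.0258), Cox6a1 (-0.54, SE 0.13, adjusted p = 0.0388) and Uqcrb (-0.61, SE 0.15, adjusted p = 0.0495) changed in the other direction. Of 34 oxidative phosphorylation genes these 3 fell (10 adjusted over the list alone, median -0.20). The list passed camera (adjusted p = 2.51e-05, adjusted p = 0.546 with an estimated correlation). Its median was -0.083 without CTR 4 and CTR 5, with a camera adjusted p of 0.208. Mitochondrially encoded genes, which are not in this list, held a lower share of the counts in KO (1.29 ± 0.0605%) than in CTR (1.70 ± 0.207%). Hk2 kept its call with any 1 library left out. Ndufa4, Cox6a1, Uqcrb and Gpi1 lost theirs without CTR 3, KO 1, KO 2 or KO 4 (adjusted p up to 0.0753, 0.111, 0.135 and 0.125), Cox6a1, Uqcrb and Gpi1 also without CTR 5, KO 3 or KO 5, Uqcrb and Gpi1 without CTR 1, and Gpi1 without CTR 2. Without CTR 4 and CTR 5 the log2 fold changes of Cox6a1 and Uqcrb were -0.33 and -0.35, and Uqcrb lost its call (adjusted p = 0.0592). With the length and GC correction Uqcrb (0.0739) and Gpi1 (0.0853) lost theirs. Slc16a3 passed without CTR 4 (0.00653) or KO 5 (0.0484).

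The cell cycle, lysosome and unfolded protein response lists passed downward with camera at the preset correlation and not at an estimated correlation. With fry the lysosome list passed (adjusted p = 0.0237), and the cell cycle (0.291) and unfolded protein response lists (0.106) did not. Of 35 cell cycle genes none passed over all genes in edgeR (0 adjusted over the list alone), with 1 higher and 8 lower at an unadjusted p under 0.05, and at an adjusted p under 0.05 1 and 4 by DESeq2 and 1 and 5 by voom. The median was -0.42, and Cdc20, an activator of mitotic exit, had -1.28 (SE 0.34, adjusted p = 0.0564, and 0.0279 without CTR 4). The list passed camera (adjusted p = 0.000671, adjusted p = 0.587 with an estimated correlation). Its median was -0.28 without CTR 4 and CTR 5, with a camera adjusted p of 0.00987. Atp6v0d1, a proton pump subunit, fell (-0.41, SE 0.07, adjusted p = 0.0150), and 2 of 26 lysosome genes fell in all (5 adjusted over the list alone, median -0.11). That list passed camera (adjusted p = 0.00593, adjusted p = 0.340 with an estimated correlation). Its median was -0.13 without CTR 4 and CTR 5, with a camera adjusted p of 0.0244. Of 21 genes of the unfolded protein and integrated stress response only Ddit4, an inhibitor of mTOR signalling, passed, and it rose (1.02, SE 0.23, adjusted p = 0.0321; 1 higher and 6 lower adjusted over the list alone, median -0.33). That list passed downward (adjusted p = 0.00312, adjusted p = 0.416 with an estimated correlation). Its median was -0.15 without CTR 4 and CTR 5, with a camera adjusted p of 0.135. Atp6v0d1 lost its call without CTR 3 or KO 2 (adjusted p up to 0.0579) and Ddit4 without CTR 1, CTR 3 or KO 1 to KO 4 (up to 0.0893).

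Heat shock and early stress response genes passed upward as a list with camera at the preset correlation, but not at an estimated correlation or with fry (adjusted p = 0.248). Klf2, a transcription factor of quiescent cells, rose (log2 fold change 0.60, SE 0.14, adjusted p = 0.0407), and Zfp36, which speeds the decay of cytokine mRNA, rose (0.46, SE 0.12, adjusted p = 0.0485). Hspe1, a mitochondrial chaperonin gene, fell (-0.60, SE 0.14, adjusted p = 0.0340, and -0.37 without CTR 4 and CTR 5). Of 20 members 2 rose and 1 fell (4 and 2 adjusted over the list alone, median 0.22), and the list passed camera (adjusted p = 0.0221, adjusted p = 0.587 with an estimated correlation). It did not pass without CTR 1, CTR 2, CTR 3 or KO 2 (adjusted p up to 0.117). Without CTR 4 and CTR 5 together its camera adjusted p was 0.000118 and its median 0.43. Klf2, Zfp36 and Hspe1 lost their call without CTR 3, KO 1, KO 2 or KO 4 (up to 0.105, 0.133 and 0.0975), Klf2 and Zfp36 also without CTR 1 or CTR 2, Klf2 and Hspe1 without CTR 5 or KO 3, and Zfp36 without CTR 4. Of the 27 lists tested 9 passed camera with a preset correlation of 0.01, 0 passed with an estimated correlation, and 17 of 100 splits of the libraries, the real one included, gave at least 9. With fry, which asks whether a list's genes move one way on balance, 5 passed: Gs-coupled receptors, MHC class II and small peritoneal markers upward, and lipid storage and lysosome downward.

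**Figure D4:**
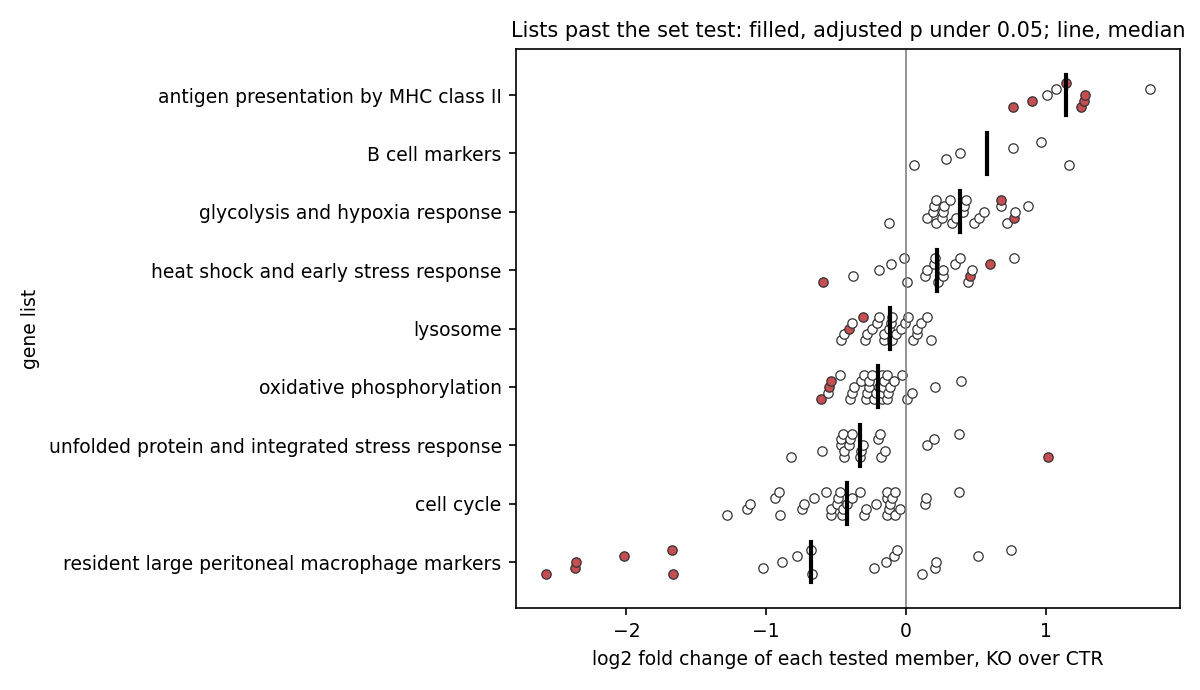
Log2 fold change, KO over CTR, of each tested member (points) of the 9 lists that passed camera, with the list median (line), 5 libraries per genotype. Filled points have an adjusted p under 0.05 over all genes. The medians run from -0.68 for resident macrophage markers to 1.14 for MHC class II.

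Several further macrophage lists did not pass. Mmp14, a membrane-bound metalloproteinase, fell from 146 ± 34.8 to 74.2 ± 17.3 CPM (log2 fold change -0.98, SE 0.19, adjusted p = 0.0204), and Spp1, which encodes osteopontin, fell from 4299 ± 817 to 2788 ± 283 CPM (-0.63, SE 0.13, adjusted p = 0.0246). With Timp1, 3 of 17 matrix proteases and inhibitors fell (3 adjusted over the list alone, list adjusted p = 0.268). The chemokine gene Ccl24 fell (-1.53, SE 0.29, adjusted p = 0.0195), as did the inhibitory receptor gene Cd200r1 (-0.40, SE 0.08, adjusted p = 0.0258), 2 of 17 genes of alternative activation (1 higher and 4 lower adjusted over the list alone, list adjusted p = 0.986). The median of that list was 0.12, while its mean and its test were negative. The cytokine gene Il1a fell (-0.43, SE 0.11, adjusted p = 0.0437), 1 of 23 inflammatory mediators (1 higher and 2 lower adjusted over the list alone, list adjusted p = 0.784), a list with a positive median and test and a negative mean. Nos2, the inducible nitric oxide synthase, had 1.59 (SE 0.45, adjusted p = 0.0694), and 1.04 (adjusted p = 0.161) without KO 4, which stood at 19.1 CPM. Of 37 interferon-stimulated genes none passed in edgeR (0 adjusted over the list alone, list adjusted p = 0.650), with 1 higher and 2 lower at an unadjusted p under 0.05, and at an adjusted p under 0.05 none by DESeq2 and 1 lower by voom. Csf1r, the receptor for macrophage colony-stimulating factor, rose (0.46, SE 0.09, adjusted p = 0.0235), and so did the integrin gene Itgam (0.79, SE 0.20, adjusted p = 0.0494). With Lyz2, 2 of 18 core macrophage genes rose and 1 fell (2 and 1 adjusted over the list alone, list adjusted p = 0.503), and Itgam was the 1 of 19 chemotaxis and adhesion receptors that rose (1 adjusted over the list alone, list adjusted p = 0.449). All of these genes that passed, Lyz2 aside, lost their call without CTR 3 or KO 2, all but Ccl24 without KO 1, and all but Mmp14 and Spp1 without KO 4. The highest adjusted p was 0.0582 for Mmp14, 0.0748 for Spp1, 0.0623 for Ccl24, 0.0781 for Cd200r1, 0.124 for Il1a, 0.0741 for Csf1r and 0.130 for Itgam. Il1a and Itgam also lost it without CTR 1, CTR 2 or KO 3, and Itgam without CTR 5. With the length and GC correction Il1a (-0.28, adjusted p = 0.173), Cd200r1 (-0.26, adjusted p = 0.0778) and Itgam (0.77, adjusted p = 0.0543) lost their call, and with library-size scaling alone Il1a did (adjusted p = 0.0736).

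Among markers of other cells of the peritoneal cavity the B cell list passed camera at the preset correlation, but not at an estimated correlation or with fry (adjusted p = 0.0577), and 1 neutrophil marker fell. The 6 tested B cell markers passed upward as a list (adjusted p = 0.0221, adjusted p = 0.386 with an estimated correlation). The list median was 0.36 without CTR 4 and CTR 5, with a camera adjusted p of 0.126. None of the 6 passed alone in edgeR (2 higher adjusted over the list alone), with 2 higher at an unadjusted p under 0.05, and at an adjusted p under 0.05 1 by DESeq2 and 2 by voom. Ighm, the immunoglobulin M heavy chain, stood at 4.18 ± 2.12 CPM in CTR and 8.16 ± 1.55 CPM in KO. The list did not pass without CTR 3, CTR 5 or KO 5 (up to 0.123). Of 5 neutrophil markers S100a8, a calcium-binding protein of neutrophils, fell (-0.56, SE 0.14, adjusted p = 0.0443; 2 adjusted over the list alone, list adjusted p = 0.784), and it lost its call without CTR 1, CTR 2, CTR 3, CTR 5 or KO 1 to KO 4 (up to 0.113), without CTR 4 and CTR 5 together (0.0672), and with the length and GC correction (0.0751). In edgeR none of 5 dendritic (0.650), 10 mesothelial (0.977) and 8 fibroblast markers (0.986) passed, over all genes or adjusted over the list alone. In each of these lists 1 was lower at an unadjusted p under 0.05, and 1 fibroblast marker was lower at an adjusted p under 0.05 by DESeq2, with no other call by DESeq2 or voom. The mesothelial and fibroblast lists had negative medians and means and a positive test. Under 5 genes were tested of the T and NK cell (2), mast cell (4), eosinophil (2), erythroid (0) and sex-linked lists (4), so these lists had no set test. None of their genes passed in edgeR, at an unadjusted p under 0.05, or at an adjusted p under 0.05 by DESeq2 (0 adjusted over the list alone), and 1 T and NK cell marker was lower by voom at that threshold. Xist had 0 counts in all libraries, and the Y-linked gene Ddx3y had between 513 and 926 counts in each.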

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

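All tests of explanations in this part were chosen only after the result was seen, except the ratio without CTR 4 and CTR 5 for the length gap and the 3 tests by other splits of the libraries. In 172 groups of 5 libraries (quality measures and named genes), 11 had a library far from the other 4 by Dixon's criterion, 6.40%, where chance gives about 1 in 20. Of these, 7 were in CTR 4 and 1 in CTR 5. CTR 4 had 17894 genes with at least 1 count (other CTR libraries 18479 to 18652), and its 10 most abundant genes held 20.4% of its counts (18.4% to 18.9%). CTR 4 also stood at 33295 CPM for Lyz2 (24310 to 25275), 4.93 for Adcy9 (7.67 to 9.11), 48.7 for Dhcr7 (61.7 to 63.7), 16.6 for Klf2 (10.3 to 11.7) and 23.4 for S100a8 (17.5 to 18.5). CTR 5 stood at 707 CPM for Lrp1 (1299 to 1610). KO 1 stood at 200.2 CPM for Abca1 (249.9 to 272), KO 2 at 2368 for Fabp5 (2728 to 2788), and KO 3 at 10.8 for Ighm (7.09 to 7.88).

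The first pattern is the set of 520 called genes, in which those lower in KO were shorter. A trend on length and GC content within libraries is argued against as the whole source of the calls, since 368 of the 520 kept call and sign once it was removed (lower 95% bound 66.7%), and so are CTR 4 and CTR 5, since 448 kept them without these libraries (lower bound 82.9%). The ratio of median lengths, higher over lower, was 2.54 with all libraries. Without CTR 4 and CTR 5 it was 0.958 (95% bounds 0.819 and 1.11). This met the outcome set beforehand for these 2 libraries as the source of the length gap, so they remain a possible source. The ratio was 2.51 (1.98 to 3.25) over the genes called both ways and 0.503 over those called only without these libraries. Genes called both ways are 448 of the 520 in which the gap was seen, so their ratio cannot weigh against this source. The ratio of 0.970 with the length and GC correction cannot decide either, since that correction removes a trend on length. With the replicate block the ratio was 4.19, and with DESeq2 it was 2.10. Processing order cannot be told apart from genotype, since 0 of the CTR library numbers in the labels lie below the highest KO number. Among 100 splits of the libraries only the real one, 1 of 100, gave as many genes, with 241 higher and 279 lower. The other splits gave at most 41 in one direction and 16 in the other. Chance is argued against for these counts but not excluded, since 1 of 100 is the smallest share these splits can give. Splits that mix the genotypes also carry any genotype difference within each part, which widens the spread and lowers their calls. For the lists, 17 of 100 splits gave at least 9, with up to 12 in another split, so chance cannot be excluded for their number.

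The second pattern is that markers of resident macrophages were lower and MHC class II genes higher in KO. B cells as the source of the MHC class II rise are argued against, since Cd74 rose from 560 to 1239 CPM, 404 times the summed rise of Cd79a, Cd79b and Ms4a1. A ratio over 50 was taken to argue against B cells, a limit assumed after the result was seen. The sum leaves out Ighm, which stood at 4.18 CPM in CTR and 8.16 CPM in KO. A lower share of large peritoneal macrophages stays open. The markers differed from a common shift by more than the libraries' spread. In 0 of 126 distinct regroupings of the libraries' residuals was the spread as wide (permutation p = 0.00787, the smallest these can give). This cannot decide, since a lower share need not shift all markers equally where other cells also express some of them. In edgeR 0 of the markers were higher over all genes and 1 was higher adjusted over the list alone. At an adjusted p under 0.05, 1 was higher by DESeq2 and 2 by voom. Dendritic cells stay open too. Of 11 listed markers 5 passed the filter on counts, and 0 of these were called (2 higher and 3 lower in value, camera adjusted p = 0.650). Batf3, a transcription factor of dendritic cells outside the list and picked after its value was seen, was higher (log2 fold change 1.22, SE 0.19). A change of expression within the macrophages by genotype was not tested against these explanations.

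The third pattern is that Gnas and Lyz2 were lower and Lyz1 higher in KO. Reads moved from Lyz2 to Lyz1 are argued against for the fall of Lyz2, since the rise of Lyz1 made up 2.95% of it, and a fixed share of Lyz2 reads counted for Lyz1 is argued against for the rise, since Lyz1 was 4.18-fold higher while Lyz2 fell. A share that changed with genotype, such as by altered sequence at the locus, was not tested and stays open, since the rise equals 5.53% of the Lyz2 level left in KO. DNA around the genes that differs between the genotypes cannot be excluded: near Lyz2 1 of 29 tested neighbours was called (exact hypergeometric p = 0.689, upper 95% bound 17.8%), and near Gnas 3 of 30 (exact p = 0.113, upper bound 26.5%), where the bound of 15% that would have excluded it was set after these counts were first seen. One untested hypothesis is that a Cre inserted at Lyz2, which the labels do not name, may lower Lyz2 itself.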

How the results depend on the processing

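The fits without CTR 4 and CTR 5 and with the length and GC correction were chosen only after the data were seen, and all others were planned. Gnas kept its direction and call in all 20 alternatives, with log2 fold changes from -3.71 to -3.39. Of the 520 called genes 0 changed sign in any alternative, and 53 (28 higher, 25 lower) kept their call in all 20. The counts of higher and lower genes stayed within 1.5 times with DESeq2 size factors, library size only, the stricter filter, the robust fit and the length and GC correction. They were 122 and 139 with no filter (more genes tested), 589 and 659 with DESeq2, 1026 and 893 with voom quality weights, 59 and 45 with the replicate block, and 694 and 491 without CTR 4 and CTR 5. With 1 library left out, fewer samples, they ranged from 32 to 484 and from 30 to 384. DESeq2 gave no adjusted p for 10405 of 24365 genes. Of 47 named genes called, 11 kept their call in all alternatives, and 36 lost it with at least 2 single libraries left out, most often CTR 3 (36), KO 2 (35), KO 1 (34) and KO 4 (33). In the other settings 28 lost it with the replicate block, 21 with no filter and 9 with the length and GC correction. Library size only lost 3, and each remaining setting lost fewer.

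The number of lists past the threshold ranged from 7 to 11 with 1 library left out. It was 6 without CTR 4 and CTR 5, 0 with an estimated correlation and 5 with fry. No list that passed changed direction in its median. Medians near 0 turned: cholesterol biosynthesis to 0.0118 with library size only, alternative activation to -0.0366 with no filter, and lipoprotein uptake to -0.0441 with the stricter filter and -0.0219 with the length and GC correction. Mesothelial and fibroblast markers turned to 0.253 and 0.0232 with voom quality weights, 0.00214 and 0.0656 with the block, and 0.30 and 0.10 without CTR 4 and CTR 5. That last fit also gave -0.0111 for cAMP components, -0.00706 for lipoprotein uptake, -0.0244 for cholesterol efflux and -0.0489 for interferon-stimulated genes. Abca1 turned to -0.0538 with voom quality weights and -0.135 without CTR 4 and CTR 5. With 1 library left out, ranges were -0.0112 to 0.216 for Abca1, -0.141 to 0.0604 for cholesterol biosynthesis, -0.0305 to 0.183 for inflammatory mediators, -0.0844 to 0.116 for interferon-stimulated genes, -0.56 to 0.36 for neutrophil, -0.18 to 0.13 for dendritic, -0.25 to 0.17 for mesothelial and -0.33 to 0.32 for fibroblast markers. Where the number of genes or samples does not show it, the cause was not tested.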

Other observations

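All genes and families in this part were chosen only after their values were seen. The family tests use the same calls that led to the choice and treat the genes of a family as independent. Their p-values are therefore descriptive only. Of 10 gene families, without pseudogenes, tested by Fisher's exact test and adjusted over the 10, subunits of the proteasome, which degrades tagged proteins, were lower in KO: 7 of 38 fell (adjusted p = 6.28e-05), among them Psmb5 (log2 fold change -1.15, SE 0.17) and Psmb2 (-0.62, SE 0.10), and the family median was -0.27. All 9 mitochondrial tRNAs tested were lower in value and 7 were called (adjusted p = 6.06e-10, median -0.95), and 4 of 13 mitochondrially encoded protein genes were called lower (adjusted p = 0.000400, median -0.54). These go with the lower share of mitochondrial counts in KO, and with the length and GC correction 4 tRNAs and 0 of the protein genes were called. Without CTR 4 and CTR 5, 5 tRNAs and 8 of the protein genes were called lower. Of 78 mitochondrial ribosomal protein genes 6 fell (adjusted p = 0.0122, median -0.19). These medians kept their sign with DESeq2 size factors and with library size only. Of 17 C-type lectin genes Clec4d, Clec4n and Clec2d fell and Clec4b1 rose (adjusted p = 0.0122 for lower), and the family median of -0.01 turned to 0.04 with library size only. Complex I subunits (2 of 36 lower, Ndufs5 and Ndufa11), cytosolic ribosomal proteins (3 of 81 lower, 1 higher), initiation factors (2 of 53 lower) and solute carriers (2 of 184 higher) did not pass.

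Several genes kept their call in all 20 alternatives. Lower in KO were Mcemp1, a membrane protein of mast cells and macrophages (-1.38, SE 0.13), Clec4d, a lectin receptor for mycobacterial glycolipid (-1.11, SE 0.12), Maoa, a monoamine oxidase (-1.36, SE 0.18), and Pf4, a platelet chemokine (-1.41, SE 0.20). Higher were Myo10, an unconventional myosin (1.19, SE 0.14), Lpin1, a phosphatidate phosphatase (1.11, SE 0.17), Smpd3, a neutral sphingomyelinase (1.26, SE 0.18), Batf3, a transcription factor of dendritic cells (1.22, SE 0.19), Chpf2, a chondroitin-chain enzyme (1.10, SE 0.12), Daglb, a diacylglycerol lipase (0.63, SE 0.08), and Tnfrsf11a, the receptor RANK (0.59, SE 0.08). Gm20479, which kept its call with any 1 library left out but was not tested with the stricter filter, had 0 counts in all CTR libraries and 12 to 72 counts in each KO library, 2.47 ± 1.296 CPM (n = 5), at least 13.7-fold higher against a floor of 3 counts per library. It overlaps other genes in the annotation, so which transcript its reads come from is uncertain.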
